A study of Homo sapiens with 168 samples.

How the data were processed

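Messenger RNA of HepG2 cells was measured in 168 libraries made with a directional kit, per the labels' protocols. Genes were quantified by RSEM 1.3.3 on the hg38 build, per the submitters' processing notes. Each deposited file holds, per the file headers, an expected count, a TPM, an FPKM and an effective length in bases for each of 60675 Ensembl genes. The expected counts were used for every test and level here, and the deposited TPM and FPKM values were not used for these. Between 6.4 and 11.2% of the genes in a library had an expected count that is not a whole number, and counts were rounded before testing. CPM, log2 changes, fold changes, percentages, correlations and p-values were computed here from the deposited expected counts. Gene symbols were taken from a separate list of gene names, which holds 56558 of the deposited identifiers, and otherwise from GENCODE v29. Chromosomes and positions are those of GENCODE v29 on hg38, which holds 57055 of the deposited identifiers.

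Per the labels, the cells received 16 extracts at 3 doses (141 libraries), 3 reference compounds (9 libraries), vehicle (9) or nothing (9). The doses of the compounds and the exposure times are not given in the sources used here, and batches are named for the controls alone. Samples were grouped by the extract code, dose and compound in the titles. The label of JGE08 names water and that of JGE07 gives no ratio, so these codes entered only the counts per extract and the alternatives that use codes 01 to 08 or 3 ratios. The treatment fields of replicate 3 of JGE07 at 500 µg/mL and of trichostatin A carry the number 2. The libraries follow each other in 9 sets, with the controls and compounds in 1 set and 2 consecutive extract codes in each of the other 8. Codes 01 and 02 of a solvent (peony and the first mixture) thus share a set, while peony and licorice lie in different sets, as do water and ethanol extracts and codes 02 to 04 and 06 to 08, and all vehicle libraries lie in a set without extracts. A difference between sets therefore cannot be separated from these contrasts at 1 dose, nor from any contrast of an extract with vehicle. The 20 µg/mL libraries of the same sets served as the comparison for it.

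Depth ran from 7.3 to 104.0 M counts per library with a median of 29.0 M. At the median depth a gene at 10 CPM has 290 counts, a counting error of 5.9%. The biological coefficient of variation from edgeR was 0.138 for controls, 0.175 for compounds and 0.128 for extracts. Intervals and floors that use counts cover counting error only. In 20 libraries (most of JGW05 and JGW06, and replicate 1 of JGW07 and JGW08) at most 0.3% of the nonzero whole-number counts were odd. If their reads were entered 2 times, their depth is 0.5 of the printed one and their counting error larger. In 19 libraries mitochondrially encoded RNA took over 20% of the counts. Replicate 2 of JGW07 at 500, 100 and 20 µg/mL and of JGW08 at 500 µg/mL lay nearest to libraries of JGE01 and JGE02, with a distance index of 1.45, 1.45, 1.69 and 1.67 against 3.78, 3.04, 15.35 and 3.66 to the nearest of their own group. Of 150 libraries of extracts and compounds 52 lay nearest to a library of their own group. In 10, the nearest own replicate was at least 2.5 times as far as the nearest library (replicate 2 of JGW07 at 500 and 20 µg/mL, replicate 3 of JGE02 at 20, replicate 2 of JGE03 at 100, replicate 1 of JGE06 at 20, replicate 3 of JGE05 at 100 and 20, replicates 1 and 3 of JGE08 at 500 and replicate 1 at 100 µg/mL), and 6 of these had a mitochondrial share over 20%. All libraries were kept, and counts without these are given where more than 1 library of the group was left.

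Distances between libraries were taken as the median over genes of the squared count difference over its sampling variance, scaled to 1 for sampling noise alone. Control libraries with the same number in batches A, B and C had an index of 0.73 to 1.29 in 18 pairs, against 2.37 to 14.2 in 54 pairs with different numbers and 1.32 to 28.65 in 148 pairs of replicates of other groups. Their counts were summed, a choice made after this check, which leaves 156 samples with n = 3 vehicle and n = 3 untreated. The design as first written used the 18 libraries with batch as a term and is among the alternatives. Whether replicate numbers pair the samples was checked by the correlation of deviations from the group means. For untreated and vehicle the 3 same-numbered pairs correlated at 0.10 to 0.32 (median 0.17). Of these samples 5 of 6 correlated best with their own number, so they are paired in the data. The values reported for them are from the fit without a term for the pair, and a fit with it is among the alternatives.

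Tests used edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM normalization, quasi-likelihood F test) with Benjamini-Hochberg adjustment and a threshold of 0.05, and calls with a log2 change of at least 1 were counted as well. Separate fits covered controls (17442 genes tested), compounds with vehicle (18685) and extracts with vehicle (18341). The 24 comparisons were vehicle minus untreated, each compound against vehicle, vorinostat against trichostatin A, peony, licorice and the 3 pooled mixtures (codes 02 to 04) of each solvent at 500 µg/mL against vehicle and against 20 µg/mL, the slope over the licorice share, the 1:1 mixture against the mean of the single herbs on the log scale, ethanol against water (codes 01 to 05), and codes 06 to 08 against 02 to 04 in water and 06 against 02 in ethanol. For the last 7 the same contrast at 20 µg/mL was also subtracted, as a test of the difference.

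The 31 gene lists (pathway targets, liver functions and markers of other cell types) were tested with camera of limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01, repeated with an estimated correlation, for lists with at least 3 tested members. Of 743 such tests 254 were called, and 111 of these also with the estimated correlation. Genes are named by a fixed rule. For each comparison it takes the 6 largest rises and 6 largest falls (4 for comparisons of dose, share, mixture, solvent and order) among called genes with a mean of at least 10 CPM in the higher group, a proper symbol and every library beyond the mean of the other group, and the 3 members with the smallest adjusted p of the 5 lists with the smallest p. The text names part of these genes. Comparisons, lists, this rule and most alternatives were fixed before the data were examined.

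Alternatives were another normalization (RLE), DESeq2 1.42.0, no filter, a term for the replicate number, each replicate number left out, a fit of the compared groups alone, single vehicle batches, the contrast at 20 µg/mL subtracted, the control libraries kept apart as first written, and, chosen after seeing the data, all-even counts divided by 2, the mitochondrial share as a covariate, libraries over 20% left out and the 4 libraries near another extract left out, also with the contrast at 20 µg/mL subtracted, and the same without the 10 libraries far from their own replicates. The pipeline was tested on simulated data with 200 changed genes per comparison. For untreated against vehicle (17083 genes, 6 samples) 97% of the genes changed by a log2 of 1 and 100% of those changed by 2 were recovered, with 6.2% false calls. For wortmannin (15501 genes, 12 samples) these were 91%, 100% and 7.7%, and for peony water at 500 µg/mL (16600 genes, 63 samples) 99%, 99% and 3.9%. In each, 0 of 20 unchanged lists were called. The simulated genes varied independently, so this does not cover lists whose members vary together. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The R package data.table, version 1.17.8, read the files. Cell sex markers were left out.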

Results

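HepG2 liver cancer cells were profiled in 168 RNA libraries after treatment with extracts of peony root, licorice root or their mixture, Jakyakgamcho-tang. Per the labels, 141 libraries carried 16 extracts at 20, 100 and 500 µg/mL, 9 carried a reference compound (wortmannin, vorinostat or trichostatin A, 3 each), and 18 were untreated or vehicle controls in batches A to C. Codes JGW01 to JGW08 are water extracts and JGE01 to JGE07 are 70% ethanol extracts, while the label of JGE08 names water. In both series code 01 is peony, 05 is licorice, 02 to 04 were mixed at 2:1, 1:1 and 1:2 and then extracted, and 06 to 08 were extracted singly and then mixed at those ratios, though the label of JGE07 gives no ratio. Of the 48 extract groups, 46 had 3 libraries, JGE07 at 100 µg/mL had 2 and JGE08 at 20 µg/mL had 1. Control libraries with the same number in batches A, B and C differed by an index of 0.73 to 1.29, where 1 is sampling noise alone, and were counted as 1 sample, which gave n = 3 vehicle and n = 3 untreated samples.

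Changes below are on the log2 scale ± standard error, with p-values of edgeR's quasi-likelihood test adjusted by the Benjamini-Hochberg method, and levels are in CPM ± standard deviation. Gene lists were tested with camera, and a list call is given with the adjusted p at the preset correlation and, where it differs in outcome, with an estimated correlation. The number beside a list count that is marked "list alone" is the number called when p-values were adjusted over the list alone. Levels of near-identical copies (EIF3CL, SULT1A2 and SULT1A3, HSPA1A and HSPA1B, AKR1C1 and AKR1C2, the MT1 genes, RGPD5) are uncertain because reads can be shared between copies. The level of ZACN is uncertain as well. All p-values measure only the spread between samples of the same fit, and nothing in the labels says that replicates came from separate cultures. Each gene has a single dispersion over all groups of its fit. The standard error of an extract contrast thus also carries the spread within the other extract groups. For CYP1A1, for example, the JGW07 libraries at 20 µg/mL were at 9.76, 754 and 10.3 CPM.

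Vehicle and untreated cells (n = 3 each) had 0 genes called by edgeR between them. AKR1C1, a ketosteroid reductase that NRF2 induces, was at 401 ± 50.3 CPM in vehicle and 481 ± 21.4 CPM in untreated cells (log2 -0.26 ± 0.10). HAMP, which encodes the iron hormone hepcidin, was at 22.7 ± 7.30 and 29.8 ± 6.77 CPM, and the lipid enzyme gene GPAM was at 141 ± 4.82 and 156 ± 4.48 CPM. Of 17442 genes tested 204 had an unadjusted p under 0.05, and DESeq2 called 4. The NRF2 antioxidant list was lower in vehicle by a median of 0.07 with 0 of 18 tested members called (0 list alone), at adjusted p = 0.0148 but adjusted p = 0.967 with an estimated correlation. Mitochondrially encoded RNA took 17.2 ± 6.0% of the counts in vehicle and 16.4 ± 2.3% in untreated samples.

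Wortmannin, an inhibitor of phosphoinositide 3-kinase, raised genes that FOXO factors induce when insulin signalling is low (n = 3 against 3 vehicle). DEPP1 (chromosome 10, 44970981 to 44978810) rose from 16.3 ± 4.81 to 285 ± 45.3 CPM (4.13 ± 0.21, adjusted p = 2.95e-07). G6PC1, the glucose-6-phosphatase gene (chromosome 17, 42900797 to 42913369), rose from 5.74 ± 1.28 to 95.1 ± 15.7 CPM (4.05 ± 0.18, adjusted p = 1.28e-07). IGFBP1, whose secreted product binds insulin-like growth factors, rose from 83.6 ± 24.7 to 982 ± 162 CPM (3.55 ± 0.33, adjusted p = 2.23e-05). FST rose by 2.81 ± 0.15 and the death ligand gene TNFSF10 by 2.29 ± 0.16. The amino acid transporter gene SLC6A14 fell from 51.7 ± 4.83 to 10.3 ± 0.377 CPM (-2.32 ± 0.14), the WNT antagonist gene DKK1 fell by 1.93 ± 0.18 on the log2 scale, and the mitotic genes CDC20 (-1.83 ± 0.15) and PLK1 (-1.60 ± 0.14) fell.

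By gene list under wortmannin, all 15 tested G2/M genes fell (15 list alone, median -1.27, adjusted p = 2.32e-18), and 14 of 17 DNA replication genes fell (16 list alone, median -0.68, adjusted p = 2.68e-12). In the FOXO and gluconeogenesis list 10 of 14 rose and 1 fell (11 and 1 list alone, adjusted p = 1.06e-08), among them PCK1 at 1.57 ± 0.15. Of the hepatocyte secreted proteins 7 of 15 rose (9 and 1 fall list alone, adjusted p = 7.53e-06). The fibrinogen gene FGA rose by 0.99 ± 0.12, TTR by 1.63 ± 0.28 and AHSG by 1.06 ± 0.18, though without replicate 3 TTR had adjusted p = 0.0776 and AHSG adjusted p = 0.0571. In the PXR and CAR drug metabolism list 4 of 10 rose (4 list alone, adjusted p = 0.000243), and in the PPAR alpha and fatty acid oxidation list 5 of 13 rose (7 and 1 fall list alone, adjusted p = 0.000295).

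Other list calls under wortmannin were lost with an estimated correlation. Of 14 autophagy and lysosome genes 4 rose (6 list alone, adjusted p = 0.000243, but adjusted p = 0.0903 with an estimated correlation), with WIPI1 at 1.35 ± 0.15. Of 8 glucocorticoid receptor targets 3 rose and 1 fell (4 and 1 list alone, adjusted p = 0.0167, but adjusted p = 0.343 with an estimated correlation). Of 5 blood cell markers 1 rose (3 list alone, adjusted p = 0.0489, but adjusted p = 0.161 with an estimated correlation). Of 18685 genes tested 2257 were called, 1121 higher and 1136 lower, and 593 of them by 2-fold or more. Without replicate 3 of every group 614 were called. The share of mitochondrially encoded RNA was 18.4 ± 1.8%.

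Vorinostat, a hydroxamic acid inhibitor of histone deacetylases, raised genes that had no count in vehicle (n = 3 against 3). NOVA2, which encodes a neuronal splicing factor, reached 24.7 ± 0.545 CPM, a rise of at least 2100-fold (adjusted p = 7.67e-10). HPCAL4 reached 19.2 ± 1.44 CPM (at least 1630-fold), STAC2 16.4 ± 1.31 CPM (at least 1400-fold) and IRGM 15.5 ± 3.78 CPM (at least 1320-fold). These folds set the vehicle at a floor of 3 counts over the group, and the floors cover counting error only. Same-numbered control libraries had an index down to 0.73, under that of sampling noise alone. If they share reads, the vehicle depth is overstated and the least folds, here and below, are lower. The immediate early gene FOS (chromosome 14, 75278774 to 75282230) rose from 0.623 ± 0.0940 to 54.1 ± 2.32 CPM (6.43 ± 0.18, adjusted p = 1.25e-11). NR0B2, which encodes SHP, fell from 39.6 ± 7.45 to 0.427 ± 0.319 CPM (-6.58 ± 0.42). The adhesion gene HEPACAM fell from 102 ± 3.37 to 0.595 ± 0.117 CPM (-7.42 ± 0.55). TYMS, which encodes thymidylate synthase, fell from 166 ± 23.8 to 7.81 ± 0.540 CPM (-4.41 ± 0.15).

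Under vorinostat 14 of 17 DNA replication genes fell (14 list alone, median -1.96, adjusted p = 7.29e-06, but adjusted p = 0.150 with an estimated correlation). All 15 G2/M genes fell (15 list alone, adjusted p = 6.44e-05, but adjusted p = 0.0785 with an estimated correlation). In the immediate early list 11 of 12 rose and 1 fell (11 and 1 list alone, adjusted p = 0.000599, but adjusted p = 0.445 with an estimated correlation), with DUSP1 at 3.33 ± 0.12. Of 8 bile acid genes 7 fell (8 list alone, adjusted p = 0.00116, but adjusted p = 0.0785 with an estimated correlation), with CYP27A1 at -3.44 ± 0.17. Of 10 polyadenylated histone genes 9 rose and 1 fell (9 and 1 list alone, adjusted p = 0.0112, but adjusted p = 0.587 with an estimated correlation). Of 15 hepatocyte secreted proteins 10 fell (10 list alone, adjusted p = 0.00644, but adjusted p = 0.121 with an estimated correlation), with APOH at -2.13 ± 0.16 and APOC3 at -2.84 ± 0.23. Of 18685 genes 13598 were called, 7305 higher and 6293 lower, and 9196 by 2-fold or more. Mitochondrial RNA made up 21.3 ± 4.3% of the counts.

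Trichostatin A, also a hydroxamic acid, raised several of the same silent genes (n = 3 against 3). HPCAL4 reached 16.1 ± 0.294 CPM, a rise of at least 1370-fold, and STAC2 reached 11.7 ± 0.547 CPM, at least 993-fold. CHGA, the chromogranin A gene of neuroendocrine granules, rose from 0.0274 ± 0.00613 to 37.3 ± 5.11 CPM (10.26 ± 0.30, adjusted p = 1.64e-11). FOS rose to 16.1 ± 1.75 CPM (4.68 ± 0.17) and the phosphatase gene DUSP6 rose by 2.71 ± 0.13. HMGCS1 (chromosome 5, 43289395 to 43313512), an early enzyme of cholesterol synthesis, fell from 438 ± 32.6 to 44.5 ± 4.84 CPM (-3.30 ± 0.14, adjusted p = 3.22e-10). The serum amyloid gene SAA4 fell by 4.30 ± 0.22 on the log2 scale and the partner of BRCA1, BARD1, by 3.70 ± 0.20.

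Under trichostatin A 20 of 23 cholesterol synthesis genes fell and 2 rose (20 and 2 list alone, median -1.48, adjusted p = 3.28e-07, but adjusted p = 0.224 with an estimated correlation). Of 17 DNA replication genes 16 fell (16 list alone, adjusted p = 4.04e-08, but adjusted p = 0.198 with an estimated correlation). Of 11 cytosolic heat shock genes 8 fell (8 and 1 rise list alone, adjusted p = 0.0176, but adjusted p = 0.285 with an estimated correlation), with HSPH1 at -2.03 ± 0.13 and HSPA8 at -1.99 ± 0.16. Of 8 acute phase genes 7 fell and 1 rose (7 and 1 list alone, adjusted p = 0.0182, but adjusted p = 0.198 with an estimated correlation). All 4 fibroblast markers tested rose (4 list alone, adjusted p = 0.0322, but adjusted p = 0.277 with an estimated correlation). Of 10 type I interferon genes 8 rose and 1 fell (8 and 1 list alone, adjusted p = 0.0461, but adjusted p = 0.276 with an estimated correlation). Of 18685 genes 12758 were called, 7043 higher and 5715 lower, and 7934 by 2-fold or more. Mitochondrially encoded RNA took 15.6 ± 7.5% of the counts. The distance index between the trichostatin A replicates ran from 7.08 to 20.0, against 2.12 to 4.01 for vorinostat. Replicate 3 of trichostatin A had 7.9 M counts.

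Compared with each other, vorinostat and trichostatin A differed in ADH4, HSPA1A and HMGCS1 among others (n = 3 each, doses not given in the sources used here). ADH4, an alcohol dehydrogenase (chromosome 4, 99123657 to 99157792), was at 1.66 ± 0.323 CPM under vorinostat and 155 ± 70.7 CPM under trichostatin A (-6.55 ± 0.33, adjusted p = 2.06e-08). NR0B2 was lower by 5.42 ± 0.42 and the aldo-keto reductase gene AKR1B10 by 4.48 ± 0.23 on the log2 scale. The chaperone gene HSPA1A was higher under vorinostat, at 427 ± 70.5 against 51.9 ± 6.30 CPM (3.03 ± 0.17), as was its partner DNAJB1 (2.75 ± 0.13). HMGCS1 was higher by 1.86 ± 0.13 and IDI1 by 2.28 ± 0.16. Of 23 cholesterol synthesis genes 18 were higher and 1 lower (18 and 1 list alone, adjusted p = 8.11e-07, but adjusted p = 0.255 with an estimated correlation). Of 8 bile acid genes 6 were lower (6 list alone, adjusted p = 0.00389, but adjusted p = 0.165 with an estimated correlation), and of 19 NRF2 antioxidant genes 10 were lower and 2 higher (10 and 2 list alone, adjusted p = 0.0172, but adjusted p = 0.349 with an estimated correlation). Between the compounds 9244 of 18685 genes differed, 3884 higher and 5360 lower under vorinostat, 4612 of them by 2-fold or more.

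Against vehicle, the number of genes called was higher at 500 than at 100 µg/mL in each of the 16 extracts, and at 500 µg/mL it was higher in JGE01 to JGE07 than in any water extract of JGW01 to JGW08. At 500 µg/mL 82 genes of 18341 were called for peony water (JGW01) and 2037 for licorice water (JGW05), against 9878 for peony ethanol (JGE01) and 8771 for licorice ethanol (JGE05). At 100 µg/mL the counts for these 4 extracts were 0, 315, 59 and 2063, and at 20 µg/mL they were 0, 33, 98 and 274. For JGW01 edgeR called 0 at both lower doses, where 603 genes at 20 µg/mL and 713 at 100 µg/mL had an unadjusted p under 0.05. For JGW07, 1433 genes were called at 20 µg/mL against 488 at 500 µg/mL. Its libraries labelled replicate 2 lay nearest to libraries of another extract, and without these and 1 such library of JGW08 the counts were 66 at 20 µg/mL and 961 at 500 µg/mL. Without 10 libraries that lay far from their own replicates, which also changes the spread used for every extract, they were 623 and 2222. For JGE05 they were then 3406 at 100 µg/mL (without replicate 3) and 1252 at 20 µg/mL (without replicate 3). At 20 µg/mL JGE02 had 997 in place of 55 and JGE06 had 618 in place of 51. At 100 µg/mL JGE08 had 1165 in place of 431, while JGE03 had 843 in place of 1431.

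**Figure D1:**
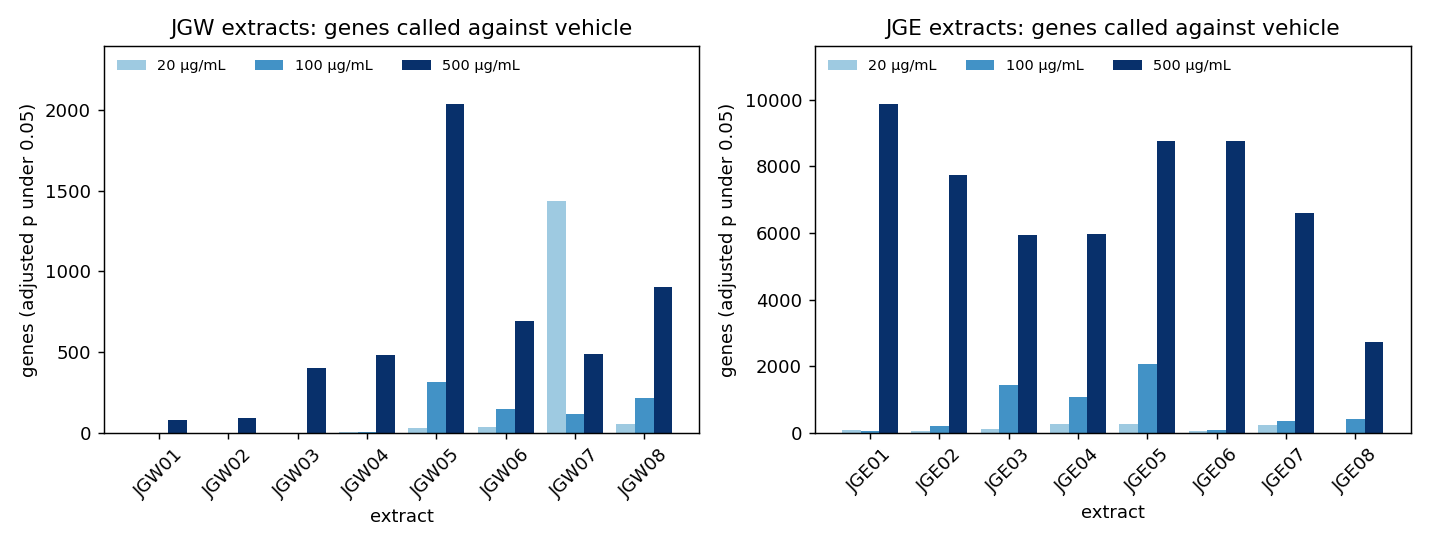
Genes called against vehicle for each extract and dose. Each bar is the number of genes with an adjusted p under 0.05 of 18341 tested, with JGW01 to JGW08 (water) in the first panel and JGE01 to JGE08 (ethanol, but water in the label of JGE08) in the second, and colours give 20, 100 and 500 µg/mL. Groups had 3 libraries except JGE07 at 100 µg/mL (2) and JGE08 at 20 µg/mL (1), against 3 vehicle samples. At 500 µg/mL the bars run from 82 (JGW01) to 2037 (JGW05) in water and from 5956 (JGE03) to 9878 (JGE01) in JGE01 to JGE07. JGE08 is at 2732, and its replicates 1 and 3 at this dose lay far from their own replicates. The bars of JGW07 and JGW08 include the libraries near another extract. Those of JGE02, JGE05 and JGE06 at 20 µg/mL each include a library far from its own replicates. So do those of JGE03, JGE05 and JGE08 at 100 µg/mL, and these counts moved when such libraries were left out.

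Peony water extract at 500 µg/mL lowered HAMP (chromosome 19, 35280716 to 35285143) from 22.9 ± 7.45 to 4.48 ± 0.560 CPM (-2.36 ± 0.31, adjusted p = 2.74e-07, n = 3 against 3). The BMP-responsive genes ID3 (-1.21 ± 0.17), ID1 (-0.98 ± 0.20) and SMAD7 (-0.75 ± 0.10) fell, as did the metallothionein gene MT1G, from 85.8 ± 33.4 to 34.5 ± 10.2 CPM (-1.31 ± 0.29, adjusted p = 0.00834). CYP1A1, the cytochrome P450 that the aryl hydrocarbon receptor induces (ENSG00000140465, chromosome 15, 74719542 to 74725610), rose from 4.04 ± 0.225 to 34.9 ± 0.643 CPM (3.11 ± 0.60, adjusted p = 0.00142). DDIT4 rose by 0.99 ± 0.24 and PDK1, which restrains pyruvate dehydrogenase, by 0.55 ± 0.13. HAMP, ID3 and SMAD7 stayed called without any 1 replicate. Without replicate 1 of every group the calls of CYP1A1 (adjusted p = 0.225) and ID1 (adjusted p = 0.0826) were lost. Those of MT1G (adjusted p = 0.379), DDIT4 (adjusted p = 0.179) and PDK1 (adjusted p = 0.185) were lost there too. CYP1A1 and ID1 were also lost without replicate 3 (adjusted p = 0.196 and adjusted p = 0.329). MT1G, DDIT4 and PDK1 were lost whichever replicate number was left out. The CYP1A1 change stayed at 3.11 without replicate 1, and its peony libraries were at 34.3, 35.6 and 34.9 CPM. In all 82 genes were called, 51 higher and 31 lower, 11 by 2-fold or more. Without replicate 1 of every group 5 were called, and 2 when the 6 samples compared were fitted alone.

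Among gene lists for peony water, 3 of 8 metallothionein and zinc genes fell (6 list alone, median -0.67, adjusted p = 3.76e-12). The glycolysis list was higher with 0 of 12 members called (5 list alone, median 0.25, adjusted p = 5.21e-09), and the G2/M list was lower with 0 of 15 called (5 list alone, median -0.21, adjusted p = 1.03e-06). In the hypoxia list 1 of 21 rose (7 list alone, adjusted p = 8.82e-09, but adjusted p = 0.144 with an estimated correlation). In the aryl hydrocarbon receptor list 1 of 8 rose (4 list alone, adjusted p = 2.87e-05), and of 4 endothelial markers 1 fell (2 list alone, adjusted p = 0.00437). Against its own 20 µg/mL dose (n = 3 each), peony water at 500 µg/mL again lowered HAMP (-2.49 ± 0.32, adjusted p = 6.05e-08) and MT1G (-1.63 ± 0.29). IGFBP1 rose from 36.0 ± 3.40 to 195 ± 17.1 CPM (2.43 ± 0.58, adjusted p = 0.0286). The call was lost without replicate 1 of every group (adjusted p = 0.202) and without replicate 3 (adjusted p = 0.334). The change was no smaller in these fits, at 2.56 and 2.45. That contrast called 69 genes, 43 higher and 26 lower, and 9 without replicate 1. Here 3 of 21 hypoxia genes rose (12 list alone, adjusted p = 5.84e-20) and 4 of 8 metallothionein and zinc genes fell (7 list alone, adjusted p = 1.75e-18). The share of mitochondrially encoded RNA was 16.9 ± 2.5% at 500 and 17.8 ± 3.1% at 20 µg/mL.

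Licorice water extract at 500 µg/mL raised CYP1A1 from 4.04 ± 0.225 to 811 ± 61.8 CPM (7.65 ± 0.71, adjusted p = 1.09e-14, n = 3 against 3). Its neighbour CYP1A2 reached 1.51 ± 0.305 CPM from no count, at least 134-fold. The NRF2 targets AKR1B10 (29.1 ± 4.93 to 239 ± 23.5 CPM, 3.04 ± 0.29), AKR1C2 (2.39 ± 0.20), AKR1C1 (2.00 ± 0.20) and GCLM, a subunit of the glutathione-making ligase (1.75 ± 0.17), rose. The stress hormone gene GDF15 rose by 1.96 ± 0.30. The sodium channel gene SCN1A fell by 1.21 ± 0.19 on the log2 scale, the bile acid reductase gene AKR1D1 by 1.11 ± 0.16 and PEG10 from 3810 ± 688 to 1770 ± 156 CPM (-1.11 ± 0.17).

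All 18 tested NRF2 antioxidant genes rose with licorice water (18 list alone, median 1.08, adjusted p = 1.90e-48), as did 7 of 8 aryl hydrocarbon receptor genes (8 list alone, median 2.35, adjusted p = 1.67e-17). In the ATF4 amino acid response list 8 of 19 rose (9 list alone, adjusted p = 2.05e-05, but adjusted p = 0.0915 with an estimated correlation). Of the hepatocyte secreted proteins 5 of 15 fell and 1 rose (8 and 1 list alone, adjusted p = 0.000172, but adjusted p = 0.101 with an estimated correlation), with the fibrinogen genes FGB at -0.57 ± 0.09 and FGA at -0.53 ± 0.10. Of 18341 genes 2037 were called, 1010 higher and 1027 lower, 348 by 2-fold or more. Without replicate 2 of every group 824 were called. Against its own 20 µg/mL dose CYP1A1 rose by 5.86 ± 0.66 (to 811 ± 61.8 CPM) and AKR1B10 by 2.57 ± 0.29, and SERPINA7, the thyroxine-binding globulin gene, fell by 1.18 ± 0.14 on the log2 scale. In that contrast 17 of 18 NRF2 antioxidant genes rose (18 list alone, adjusted p = 5.05e-40), 6 of 8 aryl hydrocarbon receptor genes rose (8 list alone, adjusted p = 2.31e-15) and 7 of 15 hepatocyte secreted proteins fell (10 list alone, adjusted p = 9.07e-08). It called 1392 genes, 668 higher and 724 lower, and 570 without replicate 1. Mitochondrial RNA made up 15.9 ± 0.7% of the counts at 500 and 17.9 ± 2.8% at 20 µg/mL.

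The 3 water mixtures extracted together, pooled at 500 µg/mL (n = 9 against 3), raised CYP1A1 to 99.8 ± 65.2 CPM (4.36 ± 0.58, adjusted p = 1.77e-07), AKR1B10 by 1.53 ± 0.25, AKR1C2 by 1.29 ± 0.17 and GDF15 by 1.23 ± 0.25. SKIL, a brake on TGF-beta signalling, fell by 0.69 ± 0.11 on the log2 scale, and the zinc exporter gene SLC30A1 by 0.36 ± 0.07. MT1F (-1.28 ± 0.22), MT1G (-1.13 ± 0.22) and HAMP (-0.97 ± 0.21) fell as well, but without replicate 1 they had adjusted p = 0.0865, adjusted p = 0.314 and adjusted p = 0.307. Of 18 NRF2 antioxidant genes 11 rose (16 list alone, adjusted p = 4.95e-29), of 8 metallothionein and zinc genes 5 fell (7 list alone, adjusted p = 3.40e-11) and of 8 aryl hydrocarbon receptor genes 4 rose (4 list alone, adjusted p = 2.91e-10). Of 12 glycolysis genes 3 rose (6 list alone, adjusted p = 2.27e-09). Of 11 fatty acid synthesis genes 3 fell (3 list alone, adjusted p = 5.83e-05). The pooled contrast called 661 genes, 306 higher and 355 lower, 84 by 2-fold or more, and 109 without replicate 1.

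Against 20 µg/mL (n = 9 each) the water mixtures raised CYP1A1 by 3.62 ± 0.36, IGFBP1 from 48.7 ± 16.6 to 189 ± 32.8 CPM (1.97 ± 0.33, adjusted p = 7.68e-06) and DEPP1 by 1.48 ± 0.21. They lowered MT1F by 1.31 ± 0.17 and MT1E by 0.90 ± 0.11 on the log2 scale, and HMGCS1 by 0.47 ± 0.09. Here 16 of 18 NRF2 antioxidant genes rose (17 list alone, adjusted p = 2.76e-39), 13 of 21 hypoxia genes rose (18 list alone, median 0.36, adjusted p = 2.50e-21) and 7 of 8 metallothionein and zinc genes fell (7 list alone, adjusted p = 2.49e-20). Of 12 glycolysis genes 7 rose (10 list alone, adjusted p = 1.49e-15), with ALDOA at 0.43 ± 0.06, and 7 of 23 cholesterol synthesis genes fell (13 list alone, adjusted p = 4.17e-13). It called 811 genes, 437 higher and 374 lower, and 299 without replicate 1. Mitochondrially encoded RNA took 16.3 ± 2.9% of the counts at 500 and 17.1 ± 2.2% at 20 µg/mL.

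Peony ethanol extract at 500 µg/mL raised IGFBP3 (chromosome 7, 45912245 to 45921874) from 0.898 ± 0.268 to 232 ± 5.21 CPM (adjusted p = 3.16e-23, n = 3 against 3). The cytokine gene IL11 rose from 1.86 ± 0.155 to 204 ± 18.7 CPM (6.78 ± 0.41), IGFBP1 from 80.2 ± 23.5 to 8680 ± 484 CPM (6.76 ± 0.70) and the endotoxin receptor gene TLR4 by 6.37 ± 0.46 from 0.193 ± 0.0902 CPM. EGLN3, a prolyl hydroxylase that HIF1 induces, rose by 5.24 ± 0.42. MT1G fell from 85.8 ± 33.4 to 4.70 ± 0.157 CPM (-4.19 ± 0.34, adjusted p = 1.72e-20). GPAM, which starts triglyceride synthesis, fell from 143 ± 4.91 to 11.4 ± 0.374 CPM (-3.64 ± 0.18), and DDC, the dopa decarboxylase gene, fell by 3.61 ± 0.18 on the log2 scale.

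All 21 tested hypoxia genes rose with peony ethanol (21 list alone, median 1.84, adjusted p = 5.87e-17). In the immediate early list 11 of 12 rose (11 list alone, median 3.00, adjusted p = 2.55e-11), with JUN at 2.10 ± 0.13 and DUSP1 at 3.07 ± 0.20. All 14 autophagy and lysosome genes rose (14 list alone, adjusted p = 2.10e-09), with the cargo receptor SQSTM1 at 2.01 ± 0.13 and cathepsin B, CTSB, at 1.16 ± 0.06. Of 17 DNA replication genes 14 fell and 1 rose (14 and 1 list alone, adjusted p = 9.49e-09), and 14 of 15 G2/M genes fell (14 list alone, adjusted p = 9.09e-08). Of 8 NF-kappa-B targets 7 rose and 1 fell (7 and 1 list alone, adjusted p = 1.24e-05). The ATF4 amino acid response list had 13 of 19 higher and 5 lower (13 and 5 list alone, adjusted p = 0.00397, but adjusted p = 0.274 with an estimated correlation). The NRF2 antioxidant list had 12 of 18 higher and 2 lower (12 and 2 list alone, adjusted p = 0.00539, but adjusted p = 0.429 with an estimated correlation). Of 18341 genes 9878 were called, 4989 higher and 4889 lower, 3542 by 2-fold or more.

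Against 20 µg/mL of the same extract (n = 3 each), IGFBP3 rose by 8.65 ± 0.62 and NDRG1, a stress gene under HIF1 (chromosome 8, 133237171 to 133302022), from 54.4 ± 12.3 to 854 ± 54.6 CPM (3.97 ± 0.28, adjusted p = 3.04e-23). MT1G fell by 4.38 ± 0.34 on the log2 scale. All 21 hypoxia genes (21 list alone, adjusted p = 3.22e-19) and all 12 immediate early genes rose (12 list alone, adjusted p = 1.59e-12), and all 15 G2/M genes fell (15 list alone, adjusted p = 5.17e-08). In the FOXO and gluconeogenesis list 12 of 14 rose and 2 fell (12 and 2 list alone, adjusted p = 0.000187). The contrast called 9504 genes, 4747 higher and 4757 lower, 3354 by 2-fold or more. The share of mitochondrially encoded RNA was 14.6 ± 2.1% at 500 and 13.9 ± 0.2% at 20 µg/mL.

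Licorice ethanol extract at 500 µg/mL gave the highest CYP1A1 level among the groups pooled here, 2400 ± 47.8 CPM (9.22 ± 0.75, adjusted p = 5.68e-20, n = 3 against 3). The water and glycerol channel gene AQP3 (chromosome 9, 33441154 to 33447633) rose from 1.51 ± 0.287 to 216 CPM (7.15 ± 0.47) and the transporter gene SLC16A6 from 7.96 ± 0.820 to 344 ± 35.5 CPM (5.43 ± 0.32). ASNS, asparagine synthetase (chromosome 7, 97852118 to 97872542), rose from 48.7 ± 2.89 to 213 ± 16.3 CPM (2.13 ± 0.08, adjusted p = 2.26e-43), and SQSTM1 from 182 ± 11.9 to 1250 ± 106 CPM (2.77 ± 0.14). CA9, the hypoxia-induced carbonic anhydrase (chromosome 9, 35673856 to 35681159), fell from 13.6 ± 0.994 to 0.413 ± 0.536 CPM (-5.02 ± 0.47). SLC6A14 fell from 49.6 ± 4.62 to 2.79 ± 0.651 CPM (-4.15 ± 0.13) and TOP2A, topoisomerase II alpha (chromosome 17, 40388516 to 40417950), from 533 ± 42.5 to 142 ± 15.7 CPM (-1.91 ± 0.07, adjusted p = 1.23e-42).

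All 17 DNA replication genes fell with licorice ethanol (17 list alone, median -1.50, adjusted p = 6.82e-29), as did all 15 G2/M genes (15 list alone, median -1.32, adjusted p = 5.59e-15). All 18 NRF2 antioxidant genes rose (18 list alone, median 1.88, adjusted p = 2.88e-22). In the ATF4 amino acid response list 16 of 19 rose and 1 fell (16 and 1 list alone, median 1.60, adjusted p = 3.11e-15), with DDIT3 at 2.48 ± 0.13. Of 14 autophagy and lysosome genes 12 rose (12 list alone, adjusted p = 5.23e-11), and all 8 aryl hydrocarbon receptor genes rose (8 list alone, adjusted p = 1.54e-07). In the PXR and CAR list 5 of 8 rose and 2 fell (5 and 2 list alone, adjusted p = 0.0181). Of 18341 genes 8771 were called, 4401 higher and 4370 lower, 2892 by 2-fold or more. Against 20 µg/mL (n = 3 each) AQP3 rose by 6.57 ± 0.48, IGFBP1 from 41.1 ± 3.69 to 2120 ± 319 CPM (5.69 ± 0.67) and ASNS by 2.12 ± 0.08, and SCN1A fell by 4.46 ± 0.25 on the log2 scale. All 17 DNA replication genes fell (17 list alone, adjusted p = 1.82e-31), and 7969 genes were called, 3876 higher and 4093 lower. Mitochondrial RNA made up 13.1 ± 1.0% of the counts at 500 and 18.8 ± 9.5% at 20 µg/mL.

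The 3 ethanol mixtures extracted together, pooled at 500 µg/mL (n = 9 against 3), raised genes of both herbs. CYP1A1 reached 1400 ± 641 CPM (8.31 ± 0.71, adjusted p = 2.10e-18), IGFBP3 51.1 ± 33.6 CPM (5.47 ± 0.50), AQP3 69.5 ± 20.7 CPM (5.47 ± 0.42) and IL11 47.1 ± 25.2 CPM (4.51 ± 0.35). The thyroid hormone deiodinase gene DIO1 fell by 2.06 ± 0.13 on the log2 scale, the alcohol dehydrogenase gene ADH6 from 89.7 ± 11.6 to 18.5 ± 5.66 CPM (-2.33 ± 0.13) and AKR1D1 by 2.42 ± 0.12. Of 18 NRF2 antioxidant genes 16 rose and 1 fell (16 and 1 list alone, adjusted p = 9.18e-18), all 12 immediate early genes rose (12 list alone, adjusted p = 4.21e-12) and 16 of 17 DNA replication genes fell (16 list alone, adjusted p = 4.61e-14). Of 21 hypoxia genes 17 rose and 1 fell (17 and 1 list alone, adjusted p = 3.97e-09, but adjusted p = 0.129 with an estimated correlation). The mixtures differed in this list between 20 and 500 µg/mL. All 21 rose in JGE02 (median 1.23) and JGE03 (median 0.94), while in JGE04 5 rose and 5 fell (median -0.06). Of 16 p53 targets 9 rose and 5 fell (9 and 5 list alone, adjusted p = 0.00614, but adjusted p = 0.122 with an estimated correlation). The pooled contrast called 7635 genes, 3758 higher and 3877 lower, 1691 by 2-fold or more. Against 20 µg/mL (n = 9 each) IGFBP1 rose by 5.91 ± 0.39 and the cystine transporter gene SLC7A11 by 2.86 ± 0.15, ACSM2B fell by 2.60 ± 0.13 on the log2 scale, and 9641 genes were called, 4737 higher and 4904 lower. Mitochondrially encoded RNA took 15.1 ± 3.3% of the counts at 500 and 13.2 ± 2.1% at 20 µg/mL.

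**Figure D2:**
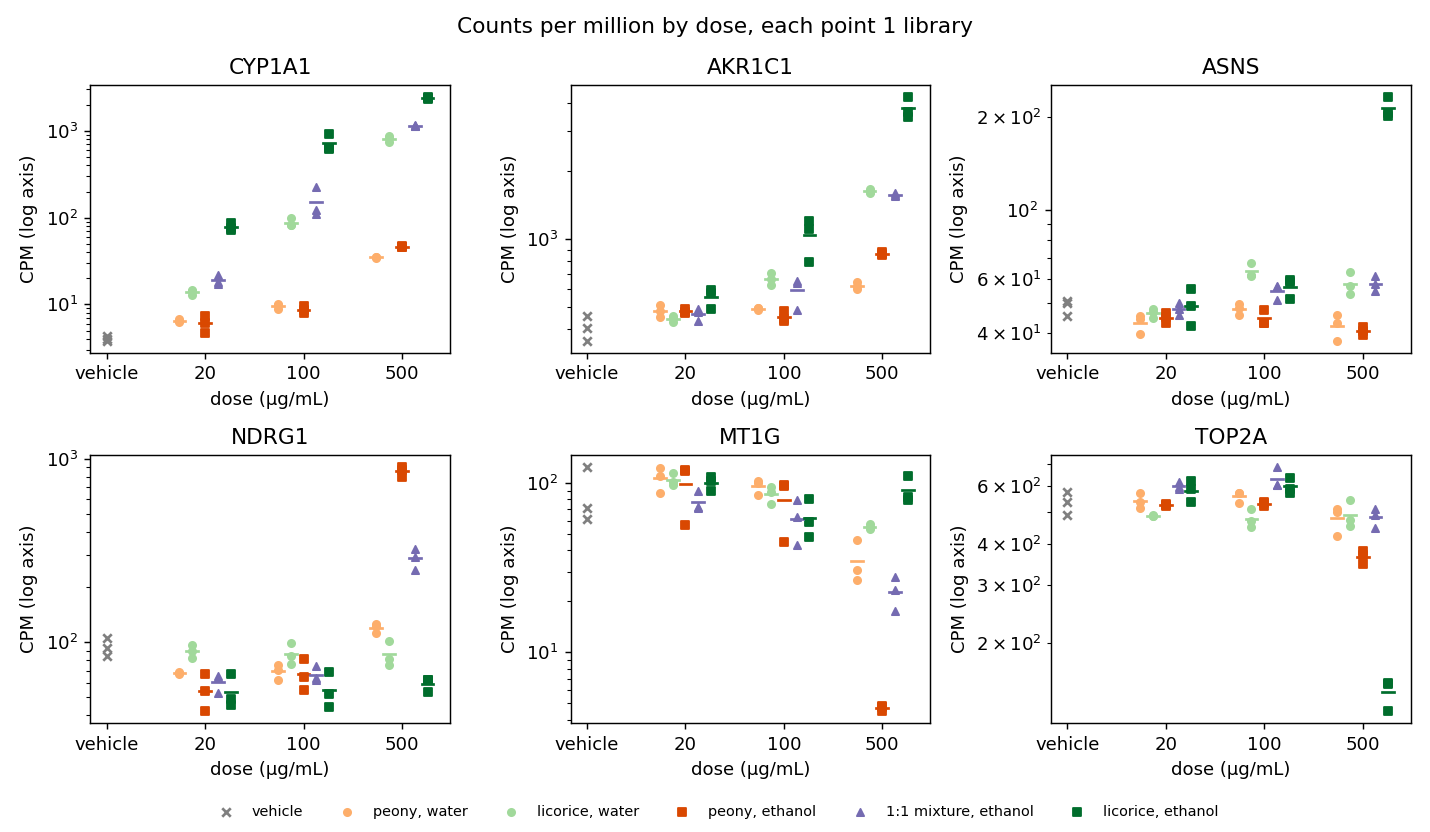
Levels of 6 genes by extract and dose. The vertical axis is CPM on a log scale and the horizontal axis is the dose (vehicle, then 20, 100 and 500 µg/mL). Each point is 1 library or summed vehicle sample and short lines mark the means of JGW01 (peony water), JGW05 (licorice water), JGE01 (peony ethanol), JGE03 (1:1 mixture ethanol) and JGE05 (licorice ethanol). CYP1A1 runs from 4.04 CPM in vehicle to 2400 CPM in JGE05 at 500 µg/mL, NDRG1 reaches 854 CPM in JGE01, MT1G falls from 85.8 to 4.70 CPM in JGE01, ASNS reaches 213 CPM and TOP2A falls to 142 CPM in JGE05.

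Across the licorice share of the 500 µg/mL water extracts (0, 1/3, 1/2, 2/3 and 1, n = 3 each), slopes are given per change of the share from 0 to 1. CYP1A1 rose by 4.71 ± 0.58 (adjusted p = 5.96e-10), HAMP by 3.64 ± 0.30 (adjusted p = 1.58e-17), AKR1B10 by 2.44 ± 0.27 and the vitamin D hydroxylase gene CYP24A1 by 2.09 ± 0.24. PLPPR1 fell by 1.57 ± 0.12 on the log2 scale, the endocytic adaptor gene DAB2 by 1.38 ± 0.18 and FGA by 0.77 ± 0.10. Of 18 NRF2 antioxidant genes 16 rose (16 list alone, median 0.84, adjusted p = 1.68e-27) and of 8 aryl hydrocarbon receptor genes 5 rose (6 list alone, adjusted p = 2.02e-09). Of 15 G2/M genes 6 rose (7 list alone, adjusted p = 7.48e-05), with AURKA at 0.57 ± 0.08. Of 9 iron handling genes 3 rose and 1 fell (3 and 1 list alone, adjusted p = 0.0378, but adjusted p = 0.205 with an estimated correlation). The trend called 2585 genes, 1262 higher and 1323 lower, and 1289 without replicate 3. When the slope at 20 µg/mL was subtracted 799 genes were called and AURKA was not (0.32, adjusted p = 0.122).

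Across the licorice share of the ethanol extracts (n = 3 each of 5 shares), hypoxia genes fell with licorice and ASNS rose. CA9 fell by 7.67 ± 0.44 on the log2 scale (adjusted p = 2.54e-30) and the glucose transporter gene SLC2A3 (chromosome 12, 7919230 to 7936275) by 5.09 ± 0.19 (adjusted p = 2.80e-45), from 1100 CPM in peony to 43.5 CPM in licorice extract. TLR4 fell by 6.56 ± 0.49 and ICAM1, an adhesion gene under NF-kappa-B, by 1.85 ± 0.12. ASNS rose by 2.62 ± 0.08 (adjusted p = 1.82e-52) and the complement receptor gene C5AR1 by 5.89 ± 0.45. CYP1A1 rose by 5.56 ± 0.60, but with the slope at 20 µg/mL subtracted by 1.74 (adjusted p = 0.0520).

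In the ethanol trend all 21 hypoxia genes fell (21 list alone, median -2.17, adjusted p = 9.46e-21) and all 8 NF-kappa-B targets fell (8 list alone, adjusted p = 2.56e-06). Of 18 NRF2 antioxidant genes 17 rose and 1 fell (17 and 1 list alone, adjusted p = 3.41e-11), of 19 ATF4 amino acid response genes 14 rose and 2 fell (15 and 2 list alone, adjusted p = 2.56e-06) and of 17 DNA replication genes 15 fell and 1 rose (16 and 1 list alone, adjusted p = 3.99e-12). Of 8 metallothionein and zinc genes 6 rose (6 list alone, adjusted p = 0.000135), and of 11 histone deacetylase genes 8 fell and 3 rose (8 and 3 list alone, adjusted p = 0.0181). Of 23 cholesterol synthesis genes 19 fell (19 list alone, adjusted p = 6.42e-05, but adjusted p = 0.146 with an estimated correlation). The trend called 9675 genes, 4550 higher and 5125 lower, and 7317 with the slope at 20 µg/mL subtracted.

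**Figure D3:**
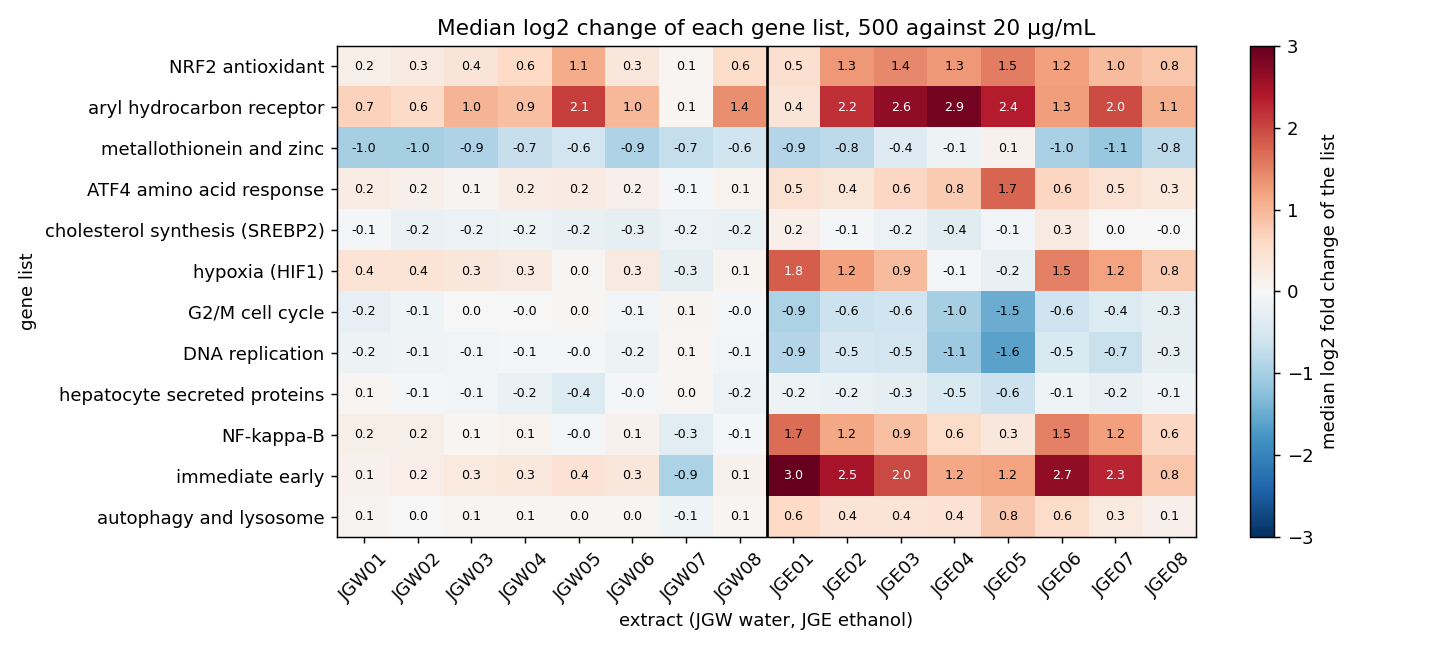
Median change of each gene list between 20 and 500 µg/mL of the same extract. Lists are down the side and the 16 extracts along the bottom, and colour is the median log2 change of the tested members, limited to 3 in either direction. Each cell compares 3 libraries with 3, except JGE08 (1 library at 20 µg/mL). Single libraries of JGE02, JGE05 and JGE06 at 20 µg/mL and a pair of JGE08 at 500 µg/mL lay far from their replicates. The columns of JGW07 (replicate 2 at 20 and 500 µg/mL) and JGW08 (replicate 2 at 500 µg/mL) include libraries that lie nearest to other extracts, and without these the aryl hydrocarbon receptor list in JGW07 is at 1.57 in place of 0.05, the immediate early list at 0.13 in place of -0.94, the hypoxia list at 0.25 in place of -0.27 and the NRF2 antioxidant list at 0.56 in place of 0.05. The hypoxia list is at 1.81 for JGE01 and the DNA replication list at -1.61 for JGE05, while the metallothionein and zinc list is at -0.99 for JGW01.

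The 1:1 water mixture was compared with the mean of the single herbs on the log scale at 500 µg/mL (n = 3 against 6). ACTA1, skeletal actin, was higher by 0.65 ± 0.13 (adjusted p = 0.00818), CDK19 by 0.36 ± 0.07 and SCN9A by 0.49 ± 0.11. The chromatin remodelling gene INO80B was lower by 0.88 ± 0.17 on the log2 scale (7.66 ± 2.82 against 14.3 ± 2.97 CPM) and the carboxylesterase gene CES1 by 0.45 ± 0.10. The NRF2 antioxidant list was lower with 0 of 18 members called (2 list alone, median -0.25, adjusted p = 4.89e-07, but adjusted p = 0.234 with an estimated correlation). In all 10 of 18341 genes were called, 7 higher and 3 lower. Without replicate 1 of every group 1 was called, and ACTA1 (adjusted p = 0.191), CDK19 (adjusted p = 0.485), SCN9A (adjusted p = 0.607), INO80B (adjusted p = 0.395) and CES1 (adjusted p = 0.348) were not. These genes also lost their calls without replicate 2, and ACTA1 and SCN9A without replicate 3 (adjusted p = 0.111 and adjusted p = 0.0602). With the same contrast at 20 µg/mL subtracted, edgeR called 0 genes and 324 had an unadjusted p under 0.05. For the contrast at 500 µg/mL DESeq2 called 50, and 67 were called with the mitochondrial share as a covariate. Mitochondrial RNA made up 19.1 ± 2.5% of the counts in the mixture and 16.4 ± 1.7% in the herbs.

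In ethanol the 1:1 mixture stood apart from the mean of the single herbs in cell cycle, autophagy and amino acid response genes (n = 3 against 6). TOP2A was at 481 ± 33.2 CPM in the mixture and 142 CPM in licorice alone, and was higher than the mean of the herbs by 1.08 ± 0.06 (adjusted p = 1.81e-29). SLC6A14 was higher by 1.96 ± 0.10 and the ribonucleotide reductase gene RRM2 by 0.94 ± 0.06. ASNS was at 57.8 ± 3.18 CPM, lower than the mean by 0.69 ± 0.07 on the log2 scale, the neuropeptide gene VGF by 2.54 ± 0.18, DDIT3 by 1.56 ± 0.12 and CTSB by 1.10 ± 0.05. All 17 DNA replication genes (17 list alone, adjusted p = 4.44e-30) and all 15 G2/M genes were higher (15 list alone, adjusted p = 1.54e-15). Of 14 autophagy and lysosome genes 11 were lower (13 list alone, adjusted p = 2.88e-11) and of 19 ATF4 amino acid response genes 14 were lower (17 list alone, adjusted p = 9.07e-11). Of 18341 genes 4998 were called, 2755 higher and 2243 lower, 2823 without replicate 1, and 1762 with the contrast at 20 µg/mL subtracted.

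Ethanol extracts differed from water extracts of the same codes (01 to 05, 500 µg/mL, n = 15 each) and had lower cell cycle genes. AQP3 was at 107 ± 61.3 against 4.55 ± 2.28 CPM (4.50 ± 0.19, adjusted p = 5.09e-40), IL11 at 75.5 ± 70.0 against 3.10 ± 0.689 CPM (4.16 ± 0.17) and IGFBP1 at 4140 ± 2740 against 211 ± 52.6 CPM (4.02 ± 0.28). SCN1A (chromosome 2, 165984641 to 166149214) was lower by 2.60 ± 0.09 on the log2 scale, ADH6 by 2.11 ± 0.08, AKR1D1 by 2.27 ± 0.08 and the replication helicase gene MCM4 by 1.05 ± 0.04. Of 17 DNA replication genes 16 were lower (16 list alone, median -0.69, adjusted p = 1.09e-17), and all 15 G2/M genes were lower (15 list alone, adjusted p = 7.74e-13). All 14 autophagy and lysosome genes were higher (14 list alone, adjusted p = 5.53e-10), with SQSTM1 at 1.54 ± 0.06. All 12 immediate early genes were higher (12 list alone, adjusted p = 4.63e-09, but adjusted p = 0.0653 with an estimated correlation). Of 15 ER chaperones 8 were higher and 2 lower (8 and 2 list alone, adjusted p = 0.0281, but adjusted p = 0.275 with an estimated correlation). Of the 13 mitochondrially encoded messages 7 were lower, and the list was not called (adjusted p = 0.226). Of 18341 genes 11047 were called, 5608 higher and 5439 lower, and 8765 with the contrast at 20 µg/mL subtracted. The share of mitochondrially encoded RNA was 14.6 ± 2.8% in ethanol and 16.4 ± 2.4% in water extracts.

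**Figure D4:**
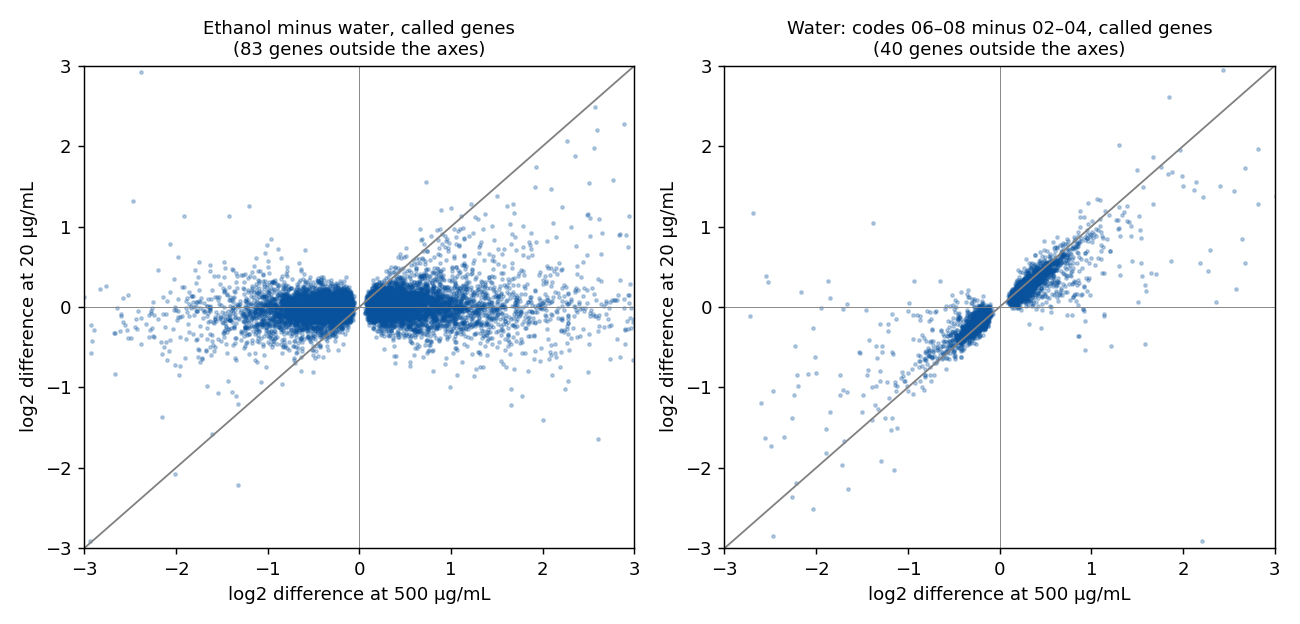
Difference between extracts at 500 µg/mL (horizontal, log2) and the same difference at 20 µg/mL (vertical, log2). Each point is a gene called at 500 µg/mL, with both axes limited to 3 in either direction and the grey diagonal marking equal differences. The first panel is ethanol minus water (11047 genes called) and the second is water codes 06 to 08 minus 02 to 04 (3717 genes called). In the first panel points lie near the horizontal axis, and in the second they lie near the diagonal, with 97.9% of genes on the same side of 0 at both doses.

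Water extracts mixed after extraction (06 to 08) differed from those mixed before it (02 to 04) at 500 µg/mL mainly by small amounts (n = 9 each). The apoptosis gene BAX was higher, at 104 ± 4.90 against 78.8 ± 8.18 CPM (0.40 ± 0.07, adjusted p = 3.54e-06), as were the histone gene H2AZ1 (0.82 ± 0.18) and the small nuclear RNA 7SK (1.71 ± 0.28). ZC3H13, part of the RNA methylation complex, was lower by 0.73 ± 0.15 on the log2 scale, XPC, a DNA damage sensor, by 0.27 ± 0.04 and JUN by 0.36 ± 0.08. EIF3CL was at 8.43 ± 5.25 against 236 ± 177 CPM (-4.60 ± 0.72, adjusted p = 1.71e-06). Of 31 lists none was called, with the metallothionein and zinc list at adjusted p = 0.193 and the NRF2 antioxidant list at adjusted p = 0.238. The contrast called 3717 genes, 1917 higher and 1800 lower, and 1515 without replicate 1. With the same contrast at 20 µg/mL subtracted edgeR called 0 genes, 768 had an unadjusted p under 0.05, and without the 4 libraries near another extract it called 1 gene, with 497 at an unadjusted p under 0.05. With all libraries the difference left in BAX was 0.07, in H2AZ1 0.09 and in ZC3H13 -0.11. Mitochondrial RNA made up 15.2 ± 1.6% of the counts in 06 to 08 and 16.3 ± 2.9% in 02 to 04.

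In ethanol the order was compared at the 2:1 ratio (JGE06 minus JGE02, 500 µg/mL, n = 3 each). The long noncoding RNA MALAT1 (chromosome 11, 65497688 to 65506516) was higher after separate extraction, at 1110 ± 72.2 against 566 ± 46.2 CPM (0.97 ± 0.22, adjusted p = 0.0128), as were the vesicle gene RAB3B (0.91 ± 0.15, adjusted p = 0.000105) and the cholesterol synthesis genes CYP51A1 (0.52 ± 0.10) and SC5D (0.48 ± 0.09). HMOX1, heme oxygenase 1, was lower by 0.51 ± 0.09 on the log2 scale and AHRR, the repressor of the aryl hydrocarbon receptor, by 1.55 ± 0.31. RAB3B stayed called without any 1 replicate, while without replicate 1 MALAT1 (adjusted p = 0.385), CYP51A1 (adjusted p = 0.124), SC5D (adjusted p = 0.0846), HMOX1 (adjusted p = 0.0973) and AHRR (adjusted p = 0.348) lost their calls. Without replicate 3 CYP51A1, SC5D, HMOX1 and AHRR were lost as well (adjusted p from 0.067 to 0.112). Without replicate 2 MALAT1 and SC5D were lost (adjusted p = 0.179 and adjusted p = 0.0677). Of 23 cholesterol synthesis genes 3 were higher (10 list alone, median 0.20, adjusted p = 9.98e-14). The hypoxia list was higher with 0 of 21 called (0 list alone, adjusted p = 5.30e-05, but adjusted p = 0.422 with an estimated correlation). The contrast called 103 genes, 68 higher and 35 lower, but 3 without replicate 1, 1198 when the compared groups were fitted alone and 2844 over 3 ratios. The 3 ratios add JGE07, whose label gives no ratio, and JGE08, whose label names water. Replicates 1 and 3 of JGE08 at this dose lay far from their own replicates. The 2844 genes thus cannot be assigned to the order. With the contrast at 20 µg/mL subtracted edgeR called 0 genes and 610 had an unadjusted p under 0.05. Mitochondrially encoded RNA took 14 ± 0.4% of the counts in JGE06 and 15.1 ± 0.9% in JGE02.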

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

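Of the tests in this part, those of the library sets, of the extraction order through the dose and of the mitochondrial share, and the values without the 4 libraries near another extract or the 10 far from their own replicates, were chosen only after the result was seen.

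A pair of results stood out because groups differed under the same contrast, each by a test of the difference itself. The difference between licorice and peony at 500 µg/mL was not the same in ethanol and water for 5767 genes (2580 higher and 3187 lower in ethanol). The change from 20 to 500 µg/mL was not the same in ethanol and water extracts of codes 01 to 05 for 8765 genes, 4291 higher and 4474 lower. In the first contrast all 21 hypoxia genes were lower (21 adjusted over the list alone, median -1.82, adjusted p = 5.38e-23) and 10 of 19 ATF4 amino acid response genes were higher and 2 lower (10 and 2 adjusted over the list alone, adjusted p = 2.24e-06).

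Water extracts mixed after and before extraction differed at 500 µg/mL in 3717 genes. An effect of the order that grows with the dose is argued against, because the median change from 20 to 500 µg/mL was 0.16 of the median difference at 500 µg/mL and no gene passed for it by edgeR (768 at an unadjusted p under 0.05), while without the 4 libraries near another extract the ratio was 0.17 and 1 gene passed, and without the 10 libraries far from their own replicates it was 0.12 and none by edgeR (523 at an unadjusted p under 0.05). The all-even counts of some libraries are argued against as well, since 95.2% of the called genes had the same sign at 20 µg/mL between libraries without such counts, against 68% of the genes not called. A difference between library sets remains open and had the value it needs, as 97.9% of the called genes had the same sign at 20 µg/mL, with and without those libraries. An effect of the order that is already full at 20 µg/mL was not tested.

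Ethanol and water extracts differed in 11047 genes at 500 µg/mL. A difference between library sets is argued against as the whole cause, since the median change from 20 to 500 µg/mL was 0.95 of the median difference at 500 µg/mL (0.92 without the 10 libraries). The mitochondrial share is argued against as the cause too, because 98% of the called genes were still called with it as a covariate. It was 14.6 ± 2.8% in ethanol and 16.4 ± 2.4% in water extracts, so the groups differed little in it. Other measures of RNA quality were not tested. An effect of the solvent on what the extract holds stays open as well, as a hypothesis found and tested on the same data.

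The 1:1 ethanol mixture differed from the mean of the single herbs in 4998 genes. Library sets are argued against as the whole cause, with 0.76 of the median difference arising between 20 and 500 µg/mL (0.70 without the 10 libraries). At 500 µg/mL 30.4% of the called genes lay outside the range of the single herbs, which averaging on a log scale alone would not give. This count cannot decide on averaging. The mixture and the herbs lie in different library sets, and the same difference at 20 µg/mL was not subtracted from it. A difference between sets can also place genes outside the range, and 74.2% of the called genes had the same sign at 20 µg/mL. A dose response steeper than linear, with each herb at a lower dose in the mixture, had the value it needs, as 75.3% of the called genes lay nearer to vehicle in the mixture than the mean of the herbs, against 56% of the genes not called. Interactions between herbs stay open and were not tested apart from this.

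Other splits of the same samples into groups of the same sizes were fitted on the compared groups alone. In some comparisons the real split alone called as many genes (1 split as large among 40, or among 24 for the solvent). Against vehicle these were the water mixtures (real count 466, highest other 1) and the ethanol mixtures (6794, 8). Against 20 µg/mL they were the water mixtures (1432, 54) and the ethanol mixtures (8966, 5004). The others were the trends in water (3147, 427) and ethanol (9583, 0), ethanol against water (10918, 31) and the order in water (5374, 1). So few splits, over 24 comparisons, do not exclude chance. Where the compared groups lie in different library sets, a difference between sets can also make the real split the largest. The split with 5004 calls put 8 of the 9 ethanol mixture libraries at 500 µg/mL on 1 side.

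Chance cannot be excluded for the mixture against the mean of herbs either, where 2 of 40 splits were as large in each solvent. The real count was 2 in water (highest other 1631) and 4856 in ethanol (highest other 5830). In both, the other split set the 3 licorice libraries in the place of the mixture, so it shows the structure of these samples, in which licorice differs from the other groups.

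For comparisons of 3 samples with 3 the 10 splits are too few for a share under 0.05. Untreated against vehicle had a real count of 0 and a highest other of 0, so 10 of the splits were as large, wortmannin 4013 and 1, vorinostat 14311 and 0, trichostatin A 11586 and 0, and vorinostat against trichostatin A 7749 and 0. Licorice water had 534 and 2 against vehicle and 991 and 2 against 20 µg/mL, peony ethanol 9801 and 0, and 11526 and 0, licorice ethanol 7034 and 0, and 5720 and 1, and the order in ethanol 1198 and 5. Peony water had 221 and 16 against 20 µg/mL. Against vehicle its real count was 2 and the highest other 224, from setting replicate 1 of peony water with vehicle samples 1 and 2, which points to a structure of the samples.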

How the results depend on the processing

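The summing of control libraries was chosen after seeing the data, and keeping them apart is the design as first written. The alternatives chosen after seeing the data were all-even counts divided by 2, the mitochondrial share as a covariate, libraries over 20% left out, and the 4 libraries near another extract or the 10 far from their own replicates left out. Of the counts of called genes 243 lay within 1.5 times the reported value and 73 did not, and where nothing else is said below the cause was not tested. With a threshold of 0.05 on 3 samples per group, small changes of genes with few counts are beyond these data, and at 10 CPM the counting error alone is 5.9% at the median depth. RLE normalization moved no median of all genes by over 0.1. For named genes the direction and call held in 5136 planned and 1589 added repeats, the call was lost in 216 and 58 and gained in 56 and 37, and the direction turned in 7 and 9.

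The block of the replicate number (pairing) gave 0 calls for untreated against vehicle and moved no other count by over 1.5 times. Outside untreated and vehicle no comparison had every same-numbered pair correlated over 0.1, the limit set for pairing. This does not show that the numbers mark no pairs. Libraries correlated best with their own number in 53 of 90 cases for the order in water (median correlation 0.02). For wortmannin they did in 0 of 6 cases (median 0.01).

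With each replicate number left out in turn, the count ranged from 614 to 1087 for wortmannin, 5 to 71 for peony water against vehicle and 9 to 55 against 20 µg/mL, 824 to 1577 and 570 to 736 for licorice water, and 109 to 397 and 299 to 508 for the water mixtures. It ranged from 1289 to 1803 for the water trend, 1 to 93 and 2823 to 4244 for the mixture against the mean of herbs in water and ethanol, 1515 to 2465 for the order in water and 3 to 16 in ethanol. Fewer samples are tested there, and the other comparisons stayed within 1.5 times in each. Among these the counts ran from 12358 to 12531 for vorinostat, 11586 to 11774 for trichostatin A, 7939 to 8765 for peony ethanol, 6459 to 8303 for licorice ethanol and 9516 to 10115 for ethanol against water.

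For untreated against vehicle DESeq2 called 4, no filter 3, the 18 libraries with batch 51 and the 18 libraries without batch 65. Both fits of 18 libraries count each control sample 3 times. With 9 vehicle libraries kept apart, for the same reason, the counts were 4739 for wortmannin, 441 for peony water, 3376 for licorice water and 2493 for the water mixtures. Fitted on the compared groups alone the counts were 4013 for wortmannin, 2 for peony water and 221 against 20 µg/mL, 534 for licorice water, 1432 for the water mixtures against 20 µg/mL, 2 for the water mixture against the mean of herbs and 1198 for the order in ethanol.

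Peony water against vehicle gave 153 calls in DESeq2, 259 with no filter, 125 with vehicle of batch B, 248 with the mitochondrial share as a covariate and 149 without libraries over 20%. Against 20 µg/mL it gave 184 with no filter and 153 with the covariate. The water mixtures gave 1231 with the covariate, 368 called against each vehicle batch, and 1273 against 20 µg/mL with the covariate. The water mixture against the mean of herbs gave 50 in DESeq2, 378 with no filter, 67 with the covariate and 4 without libraries over 20%. The order in ethanol gave 245 in DESeq2, 205 with no filter, 281 with the covariate, 315 without libraries over 20% and 2844 with 3 ratios.

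With the contrast at 20 µg/mL subtracted, the counts were 799 for the water trend, 0 and 1762 for the mixture against the mean of herbs in water and ethanol, 0 for the order in water and 0 in ethanol. Of the list calls 111 held with an estimated correlation. The named genes whose direction turned did so with the 20 µg/mL contrast subtracted (EIF3CL at -0.14 for the ethanol mixture, and for the order in water ZACN -1.08, MT-ND6 0.14, SAA4 -0.03, HAMP -0.05 and C3 0.01), except CTSB in the order in ethanol with 3 ratios (-0.15).

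With the 4 libraries near another extract left out, JGW07 gave 961 calls at 500 µg/mL in place of 488, 139 at 100 in place of 117 and 66 at 20 in place of 1433, JGW08 gave 1488 at 500 in place of 905, and the order in water gave 3670, or 1 with the contrast at 20 µg/mL subtracted too. There ZACN was at -1.06, MT-ND6 at 0.12, SESN1 at -0.02, HAMP at -0.02 and JUN at 0.00, against the direction at 500 µg/mL. Without the 10 libraries far from their own replicates the counts were 7784 for licorice ethanol and 10309 for the ethanol mixtures against 20 µg/mL and 5436 for the order in water. With the contrast at 20 µg/mL subtracted too they were 2713 for the ethanol mixture against the mean of herbs, 0 for the order in water and 6 in ethanol, and 8010 and 9537 for the ethanol trend and ethanol against water. There EIF3CL was at -0.51 for the ethanol mixture, and for the order in water ZACN was at -1.10, MT-ND6 at 0.11 and SAA4 at -0.01.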

Other observations

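The overlaps in this part were not in the design as first written, and no test was made on them. Between the herbs in ethanol, changes from 20 to 500 µg/mL overlapped in part without sharing a library. Peony and licorice shared 2028 genes that rose, where independent lists would share 1003.2, and 2106 that fell, against 1061.6. Across genes, which are not independent replicates, their changes correlated at 0.32. Licorice extracted in water and in ethanol shared 417 rising genes (141.2 for independent lists) and 492 falling genes (161.6). Peony in water and ethanol shared 37 rising genes (11.1) and 21 falling genes (6.7).

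NDRG1 graded between the herbs in the ethanol extracts at 500 µg/mL, unlike the 30.4% of genes called for the 1:1 mixture that lay outside the range of the herbs. It was at 854 CPM in peony alone, 411, 287 and 107 CPM in the 2:1, 1:1 and 1:2 mixtures and 59.3 CPM in licorice alone (n = 3 each). At 20 µg/mL peony and licorice alone were at 54.4 and 53.9 CPM, and vehicle, in another library set, at 94.1 CPM.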
